A study of Homo sapiens with 4 samples.

How the data were processed

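The data were 4 Agilent whole human genome arrays of PrEC cells, each with RNA of treated cells in Cy5 and RNA of untreated cells in Cy3. Per the labels, cells at partial confluence received 50 µM of an amino acid in water, total RNA was isolated with Trizol and purified on silica columns, and amplified RNA was labelled with cyanine dyes through a T7 promoter primer. The protocol also names leucine and glycine, which were not analysed here. The labels call both arrays of a treatment technical replicates and name untreated cells as the reference of all 4 arrays. Whether the 4 Cy3 samples came from 1 untreated extract is not stated, and they were treated as 1.

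Spot intensity values in the deposited scanner files were, per the file headers, the mean pixel brightness of the spot and the median brightness of its local background in each channel, from Agilent Feature Extraction 9.5.1.1, with no normalization. The same deposited files also hold processed intensity values that the authors' software had corrected for background, detrended and normalized between dyes with linear and lowess steps, per the file headers. The log10 ratios deposited with the series are log10 of Cy5 over Cy3 processed signal, per the file headers. The deposited series table was checked against them: 45015 of 45015 features on each array equalled the scanner's log10 ratio rounded to 3 digits. The deposited log10 ratios were converted to log2 for the alternatives, and all log2 ratios reported were computed here from the deposited intensity values.

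Each array had 45015 features, of which 43376 were not controls, for 41000 probes. Between 105 and 205 spots per array carried the scanner's outlier mark and were left out, and 0 were saturated. Background was corrected with normexp at an offset of 50, log2 ratios of Cy5 over Cy3 were normalized with loess within each array with control spots at weight 0, and spots of a probe were averaged. These steps used R 4.3.3 with limma 3.58.1 and version 1.17.8 of the data.table package. Later steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Before loess the median log2 ratio was 0.75 and 0.63 on the sarcosine arrays and 0.44 and 0.51 on the alanine arrays.

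Probes were named by RefSeq accession (23680 probes), by symbol (2802) or by an older symbol (1128), and 13390 had no name. Probes of the Y chromosome and of XIST were left out (133 probes). Probe positions are those of the array annotation on hg18, and what exon or untranslated region lies there was not looked up. A gene was represented by its probe with the highest mean log2 intensity over the 4 arrays. It was measured in a comparison when that probe was well above background in both channels on every array of the comparison.

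There were 3 comparisons: sarcosine over untreated, alanine over untreated, and sarcosine over alanine as the difference of their log2 ratios. Since each treatment is 1 sample, a size rule took the place of a test. A gene passed when all its arrays gave at least a 1.5-fold change in the same direction, or, for sarcosine over alanine, when all 4 differences between a sarcosine and an alanine array did. The SD is that of the 2 arrays of a treatment, and for a difference it is the root of the summed squares of both SDs. It covers array error and not the variation between cultures. Data were simulated with 1 noise SD for all genes, pooled from the duplicates. All genes set at 2-fold or 3-fold passed, 10 to 16% of genes set at 1.5-fold passed and 0 unchanged genes passed. Measured noise differed between genes, so this checks the rule and gives no error rate. Genes dim in 1 channel on every array were given a fold against the dim reading or, where higher, the lowest signal of that channel well above background. A dim reading is noisy, so this fold is approximate.

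For 30 gene lists of pathways, cell types and RNA quality, the median log2 ratio of the measured members was placed among 10000 random lists of the same size matched on mean log2 intensity in 20 bins. A list stood apart when its percentile was under 2.5 or over 97.5, with at least 5 measured members. This describes these arrays and is no test of the treatment. The similarity of both ratios was set against 100 simulations of unchanged extracts that shared 1 untreated extract.

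The genes named were the 12 highest and the 12 lowest past the size rule in each comparison, up to 4 members of each list with the largest absolute ratio, and a fixed set whatever their values, among them SARDH, DMGDH, GNMT, PIPOX, SHMT1, SHMT2, GPT2, EGFR and SRC. The text gives those that show the range of each group. Genes named beyond this rule were picked after their values were seen: PDIA3, the genes dim in 1 channel, members of the lists added later, and genes named in 1 comparison whose value is given in another. The lists, the size rule, the naming rule and most alternatives were fixed before the data were examined.

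The alternatives set beforehand were the scanner's own ratios, the ratios of the series matrix, median centring in place of loess, between-array Aquantile and scale steps, no background correction, a normexp offset of 16, no filter on dim probes, brighter probes alone, the mean of a gene's probes, a 2-fold threshold, a threshold on the mean of arrays, random lists not matched on intensity, same-slide pairs and each array left out. Array-level limma fits, with and without a slide block, were planned as a description of array noise, at an adjusted p of 0.05. Spike-in scaling, values within each slide, centring on the measured genes or within intensity bins, the demand that every probe of a gene passes, and 3 added lists, 2 of them also without the gene that prompted them, were chosen after the data were seen.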

Results

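RNA abundance was measured in PrEC cells, human prostate epithelial cells in primary culture, after exposure to sarcosine or alanine. Sarcosine is N-methylglycine and is a structural isomer of alanine, so the pair compares an amino acid with its methyl group on the nitrogen and an amino acid with it on the alpha carbon. The labels give 50 µM for both amino acids. The series title gives a time of 6 h and the treatment protocol gives 24 h, so the exposure time of these samples is not settled here. Each of 4 whole-genome arrays carried RNA of treated cells in the Cy5 channel and RNA of untreated cells in the Cy3 channel, with 2 arrays for sarcosine and 2 for alanine. The labels call the arrays of a treatment technical replicates, so each treatment is 1 sample and no p-value for a treatment is given. Between 41.6% and 48.6% of the probe spots were well above background in Cy3 on the 4 arrays, and between 56.6% and 64.5% in Cy5. Across genes, which are not independent replicates, the duplicate arrays correlated with r = 0.980 for sarcosine and r = 0.987 for alanine. The median SD of the duplicates was 0.07 log2 units for sarcosine and 0.05 for alanine. The number of arrays limits the precision of every value.

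All log2 ratios are relative to the array's loess curve, at which the median of the measured genes lay at 0.01 for sarcosine over untreated, 0.03 for alanine over untreated and −0.04 for sarcosine over alanine. Centring each array on its median over all probes moved these medians to 1.31, 0.94 and 0.31. Scaling to the spike-in offsets in the scanner headers moved them to 0.74, 0.40 and 0.31. That scaling shifts all genes of an array alike, so it can turn the sign of a gene list's median but left the percentile of every list that stood apart as it was. A gene passed the size rule when every array of the comparison gave at least a 1.5-fold change in the same direction. In what follows, a value with ± is a mean log2 ratio with its SD (n = 2 arrays per treatment), and only genes past the size rule are said to have risen or fallen.

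The comparison of sarcosine with untreated cells asks which transcripts changed after this amino acid. The highest ratio belonged to MAT2A, which makes S-adenosylmethionine from methionine, at 5.35 ± 0.02 or 40.9-fold (probe on hg18 chromosome 2, 85625813 to 85625872). Its other probe gave 4.59. TRA2B, a splicing regulator, rose by 3.98 ± 0.06, the RNA-binding protein gene RBM14 by 3.77 ± 0.09 and ODC1, the first enzyme of polyamine synthesis, by 3.53 ± 0.04. At the other end, the circadian repressor NR1D1 was at −3.76 ± 0.10, or 13.5 times lower, and DDIT3, the stress transcription factor CHOP, at −3.74 ± 0.10, or 13.4 times lower. TP63, the master regulator of basal epithelium, fell by 3.12 ± 0.04, which is 8.68 times lower.

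Heat shock genes stood above other genes of like intensity with sarcosine. Of 14 measured members, 9 were higher, 2 lower and 3 neither, and the list median of 0.84 lay at percentile 99.98 of random lists. HSPA1A, the inducible HSP70 chaperone, rose by 3.58 ± 0.02, its partner DNAJA1 by 2.42 ± 0.01 and HSP90AA1 by 1.34 ± 0.06. Unfolded protein response genes stood above as well, with 8 higher, 2 lower and 5 neither of 15, a median of 0.66 and percentile 99.81. HSPA5, the main chaperone of the endoplasmic reticulum, was at 2.58 ± 0.03 on its brightest probe and 1.26 on its other probe. DNAJB9, its cochaperone, rose by 2.21 ± 0.06. HERPUD1, which acts in the degradation of misfolded proteins, went the other way at −2.99 ± 0.03.

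Cell proliferation genes stood below other genes, with 1 higher, 18 lower and 8 neither of 27, but their median of −0.77 became 0.32 under median centring, −0.04 under spike-in scaling, −1.31 with the scanner's own ratios and −1.24 with brighter probes alone. Its percentile was 0 in each case. The ubiquitin-conjugating enzyme UBE2C was at −2.20 ± 0.07, thymidine kinase TK1 at −2.17 ± 0.01 and the transcription factor E2F1 at −1.81 ± 0.11. Sterol synthesis genes had 0 higher, 10 lower and 10 neither of 20, with a median of −0.64 at percentile 0.01 that became 0.86 under median centring and 0.09 under spike-in scaling. Mevalonate kinase MVK was at −1.79 ± 0.11. Glucocorticoid and retinoid responsive genes had 1 higher, 7 lower and 7 neither of 15, with a median of −0.41 at percentile 1.79 that became 1.20 under median centring and 0.32 under spike-in scaling. The phosphatase gene DUSP1 of that list was at −2.27 ± 0.17. The percentile of this list left the lower tail under 6 alternatives, among them 3.95 with the scanner's own ratios and 2.57 without sarcosine replicate 2.

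Of the 27 lists with enough measured members, these 5 stood apart and 22 did not, where chance sets apart 5% of lists. Amino acid and integrated stress response genes, targets of ATF4, had 5 higher, 4 lower and 9 neither of 18, a median of 0.32 and percentile 93.07. Its members parted, with the stress factor ATF3 at 1.32 ± 0.03 and PPP1R15A, which restores translation, at −1.85 ± 0.16. Interferon-stimulated genes had 7 higher, 1 lower and 13 neither of 21 and percentile 84.6. IFIT2, IFIT1 and OASL, antiviral genes of that list, rose by 3.54 ± 0.04, 2.30 ± 0.04 and 2.37 ± 0.04. ERK-dependent immediate early and feedback genes had 4 higher, 4 lower and 13 neither of 21, at percentile 36.47. EGFR and SRC signalling components had 4 higher, 1 lower and 19 neither of 24, at percentile 83.88, with the adaptor gene GRB2 at 1.38 ± 0.03. EGFR itself was at −0.00 ± 0.11 and SRC at 0.12 ± 0.10, or at 1.11 and 1.47 under median centring.

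In all, 3169 of 9904 measured genes (32.0%) passed the size rule with sarcosine, 1830 higher and 1339 lower. The higher genes made up 57.7% of these, against 44.1% with the scanner's own ratios, 99.2% under median centring and 96.1% under spike-in scaling. At a 2-fold threshold 1281 genes passed, and with brighter probes alone 1898 passed. Since the untreated RNA was in Cy3 on every array, gene-specific dye bias stays in these ratios.

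The same question was asked of alanine. MAT2A again had the highest ratio, at 5.37 ± 0.05 or 41.4-fold. IFIT2, an interferon-induced antiviral gene, rose by 4.34 ± 0.04, which is 20.3-fold, RBM14 by 4.19 ± 0.12 and TRA2B by 4.16 ± 0.10. TXNIP, an inhibitor of glucose uptake and of thioredoxin, rose by 3.57 ± 0.15. DNAJB5, an HSP40 family chaperone, was at −3.68 ± 0.01, DDIT3 at −3.64 ± 0.02, NR1D1 at −3.26 ± 0.02 and TP63 at −3.10 ± 0.05.

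Genes of the amino acid and integrated stress response stood above other genes with alanine, with 8 higher, 5 lower and 4 neither of 17, a median of 0.60 and percentile 99.54. Under median centring the percentile was 96.02. ATF3 rose by 2.41 ± 0.03 and asparagine synthetase ASNS by 1.25 ± 0.07, while DDIT3, a member of the same list, fell. Unfolded protein response genes had 8 higher, 1 lower and 7 neither of 16, a median of 0.66 and percentile 99.87. ERN1, the sensor IRE1, was at 2.93 ± 0.01 on its brightest probe (hg18 chromosome 17, 59560092 to 59560151). Its 2 other probes were too dim to read, among them 1 close by (59561523 to 59561582). All ERN1 values thus rest on 1 probe, and whether it reads the main ERN1 transcript is not settled. DNAJB9 was at 2.43 ± 0.03, HSPA5 at 1.46 ± 0.02 and HERPUD1 at −1.79 ± 0.15. Heat shock genes had 8 higher, 2 lower and 4 neither of 14, a median of 0.67 and percentile 99.81, with HSPA1A at 3.43 ± 0.04 and DNAJA1 at 2.05 ± 0.08.

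Cell proliferation genes had 1 higher, 15 lower and 11 neither of 27 with alanine, at percentile 0 and with a median of −0.77 that became 0.13 under median centring, −0.40 under spike-in scaling and −1.19 with the scanner's own ratios. The replication helicase genes MCM2 and MCM7 fell by 1.59 ± 0.02 and 1.45 ± 0.04. Sterol synthesis genes had 0 higher, 11 lower and 9 neither of 20, at percentile 0 and with a median of −0.80 that became 0.50 under median centring and −0.43 under spike-in scaling. MVK was at −1.63 ± 0.05 and MVD, also of the mevalonate pathway, at −1.59 ± 0.04. Glucocorticoid and retinoid responsive genes had 0 higher, 6 lower and 9 neither of 15, at percentile 0.97 and with a median of −0.35 that became 0.87 under median centring and 0.02 under spike-in scaling. DUSP1 was at −2.01 ± 0.02. The clock gene PER1 was at −1.91 ± 0.02 on its brightest probe and at 1.51 on its other probe, so its direction is not settled. The percentile of this list was 6.53 with brighter probes alone, 3.94 with the mean of a gene's probes and 2.64 under median centring. Invasion proteases and their inhibitors had 3 higher, 4 lower and 13 neither of 20, at percentile 2.02 and with a median of −0.25 that became 1.01 under median centring and 0.12 under spike-in scaling. Their members went both ways, with SERPINB5, the inhibitor maspin, at 1.73 ± 0.06, gelatinase MMP9 at 1.06 ± 0.06 and the plasminogen activator PLAU at −1.59 ± 0.02. That list no longer stood apart with the scanner's own ratios (percentile 8.47), with brighter probes alone (17.0), under median centring (28.0) or with no filter on dim probes, where its median was −0.01 at percentile 28.7.

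The other 20 lists did not stand apart with alanine. In all, 2854 of 10108 measured genes (28.2%) passed the size rule, 1886 higher and 968 lower. The higher genes made up 66.1% of these, against 47.2% with the scanner's own ratios, 98.9% under median centring and 91.5% under spike-in scaling. At a 2-fold threshold 1088 genes passed, and with brighter probes alone 1697 passed.

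Most genes that moved with sarcosine moved the same way with alanine. Among 9753 genes measured on all 4 arrays, 1390 were higher with both, where independent lists of these sizes would share 345.2, and 754 were lower with both, where they would share 132.6. These were 76.7% of the higher and 56.4% of the lower genes of sarcosine. MAT2A, TRA2B, HSPA1A and ODC1 were among the shared higher genes, and NR1D1, DDIT3, TP63 and TGM1, a cornification enzyme, among the shared lower genes. Of the genes called with both treatments, 0 had opposite directions. Across genes the ratios correlated with r = 0.906, and 85.8% of genes had the same sign. In simulated extracts without any change that shared 1 untreated extract, r was 0.477 and the covariance 0.0428, against a measured covariance of 0.438. Both ratios were taken against untreated RNA, treated as 1 extract, in the same dye orientation, and part or all of the excess may come from that shared RNA. The simulation held no dye bias and took the spread of the extracts from the difference between the treatments.

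**Figure D1:**
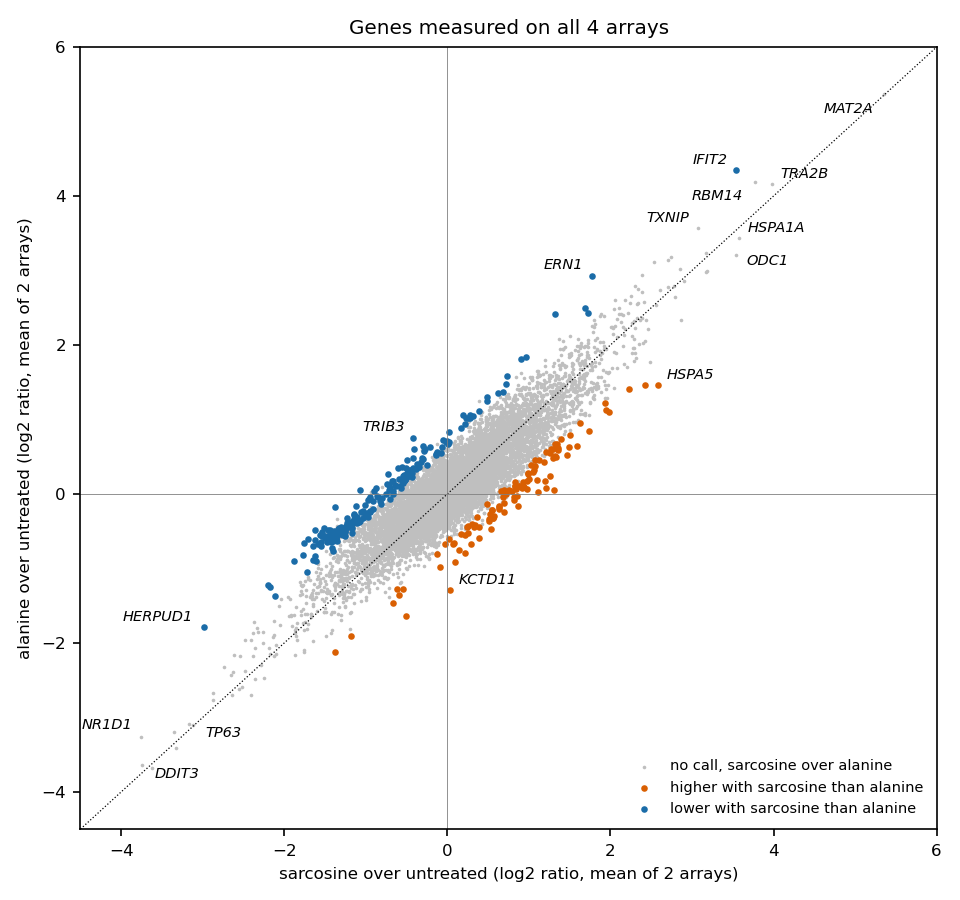
Each point is a gene measured on all 4 arrays, with the mean log2 ratio over untreated of the sarcosine arrays on the horizontal axis and of the alanine arrays on the vertical axis; orange and blue points are the 106 genes higher and the 200 genes lower with sarcosine than with alanine, and the dotted line marks equal ratios. The genes follow the line (r = 0.906), from MAT2A at 5.35 and 5.37 to DDIT3 at −3.74 and −3.64.

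The direct comparison of the isomers at the same dose leaves out gene-specific dye bias that is equal on all arrays, and leaves out the untreated RNA if the 4 Cy3 samples were 1 extract, which the labels do not state. KCTD11, an adaptor of a ubiquitin ligase, differed most in the upward direction, at 1.33 ± 0.10: it was at 0.04 ± 0.10 with sarcosine and at −1.30 ± 0.01 with alanine. EEF1A1, a translation elongation factor, was higher with sarcosine by 1.03 ± 0.01, with 1.26 against 0.24. The pseudokinase gene TRIB3, a stress target, was lower with sarcosine at −1.18 ± 0.06, with −0.42 ± 0.04 against 0.76 ± 0.03, and its other probe gave −0.37. Under median centring the TRIB3 values were 1.21 and 2.15. ATF3 was lower with sarcosine at −1.09 ± 0.04, and its other probe was too dim to read. The mitotic kinase PLK1 was lower at −1.10 ± 0.05, with −1.76 against −0.66, and its other probe gave −0.23, under the size rule.

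Among stress genes of the endoplasmic reticulum, single genes passed in both directions, while the unfolded protein response list as a whole did not stand apart, with 1 higher, 2 lower and 12 neither of 15 and a median of 0.01 at percentile 82.36. HERPUD1 was lower with sarcosine at −1.20 ± 0.16 and ERN1 at −1.16 ± 0.13, each on 1 probe. HSPA5 was higher with sarcosine by 1.12 ± 0.04 on its brightest probe, but its other probe gave −0.17, so its difference rests on 1 probe. ERP29 and PDIA3, which help proteins fold in the same compartment, were higher by 1.01 ± 0.04 and 0.92 ± 0.11. ERP29 had 1 probe, and the other probes of PDIA3 gave 0.78 and 0.70.

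Between the isomers 1 of 27 lists stood apart and 26 did not, which is no more than the 5% of lists that chance sets apart. It was serine synthesis and folate one-carbon enzymes, with 0 higher, 1 lower and 11 neither of 12 and a median of −0.37 at percentile 0.25, which became 0.01 under median centring at percentile 0.23 and −0.02 under spike-in scaling. Within slide 1 the median was −0.38 (percentile 0.61) and within slide 2 −0.38 (percentile 0.04). MTHFD2, the mitochondrial folate dehydrogenase, passed at −0.69 ± 0.12. MTHFD1L and TYMS did not, at −0.60 ± 0.15 and −0.45 ± 0.03, and the other probes of MTHFD1L gave −0.08, −0.07 and 0.27. Cell proliferation genes had 0 higher, 5 lower and 22 neither of 27, a median of −0.13 and percentile 12.14, with UBE2C at −0.98 ± 0.13, CDK1 at −0.95 ± 0.06 and TK1 at −0.93 ± 0.13. Heat shock genes had 1 higher, 0 lower and 13 neither of 14 at percentile 92.17, and the member that passed was HSP90AA1 at 0.68 ± 0.06. Amino acid and integrated stress response genes had 0 higher, 2 lower and 15 neither of 17, a median of −0.16 and percentile 23.77. Alanine and pyruvate enzymes had 2 higher, LDHA at 0.89 ± 0.08 and LDHB at 0.64 ± 0.04, of 16, at percentile 92.71. The other probes of LDHA gave 0.04 and 1.25.

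**Figure D2:**
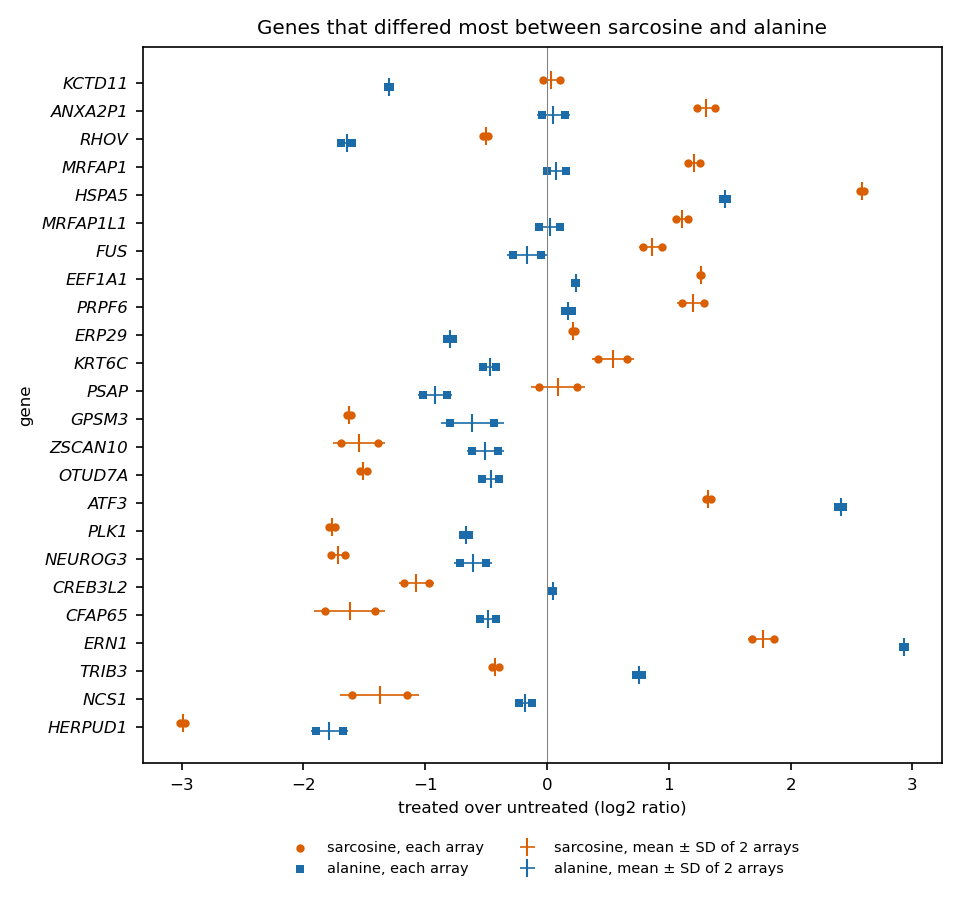
The horizontal axis gives the log2 ratio over untreated for the 12 genes highest and the 12 lowest with sarcosine relative to alanine, named on the vertical axis; points are single arrays, and bars are the mean ± SD of 2 arrays per treatment. TRIB3 lies at −0.42 with sarcosine and 0.76 with alanine, and HSPA5 at 2.58 and 1.46, a difference that its other probe (−0.17) does not show.

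Among the genes furthest from untreated, the size of the difference between the isomers varied. For MAT2A it was −0.02 ± 0.06, though its other probe gave 0.48 and it was −0.68 after the spread of the arrays was made equal. For TP63 it was −0.02 ± 0.06 and for DDIT3 −0.10 ± 0.10, which the same step moved to 0.36 and 0.35. IFIT2 was lower with sarcosine at −0.81 ± 0.06, and TXNIP was at −0.51 ± 0.23. ERK-dependent immediate early and feedback genes had 0 of 20 past the size rule, with a median of 0.03 at percentile 86.15. EGFR and SRC signalling components had 0 of 23, with a median of 0.04 at percentile 86.03. EGFR differed by −0.03 ± 0.13 and SRC by 0.18 ± 0.10.

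In all, 306 of 9753 genes (3.14%) passed the size rule between sarcosine and alanine, 106 higher and 200 lower, and 12 passed at a 2-fold threshold. When every measured probe of a gene had to pass, 222 genes did, 80 higher and 142 lower. Among genes with several measured probes, 165 had any probe past the rule and 13 had all of them past it. Over untreated these numbers were 1186 and 427 with sarcosine, and 1061 and 362 with alanine. The slides split the arrays across the treatments, with replicate 1 of both on slide 1 and replicate 2 of both on slide 2. With pairs on the same slide as blocks 410 genes passed, within slide 1 863 and within slide 2 523. The slides against each other and the crossed pairs gave 0 genes each by the same rule. Both of these splits ask that the duplicates of each treatment differ 1.5-fold, as 0.36% of genes did for sarcosine and 0.04% for alanine. Their counts were thus nearly fixed by the duplicates and are no yardstick for the 306. Without sarcosine replicate 2 the count between the isomers was 596 and without alanine replicate 2 it was 510. The higher genes made up 34.6% of the calls, against 50.0% when centred on the measured genes, 58.9% when centred within intensity bins, 99.0% under median centring and 99.0% under spike-in scaling.

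**Figure D3:**
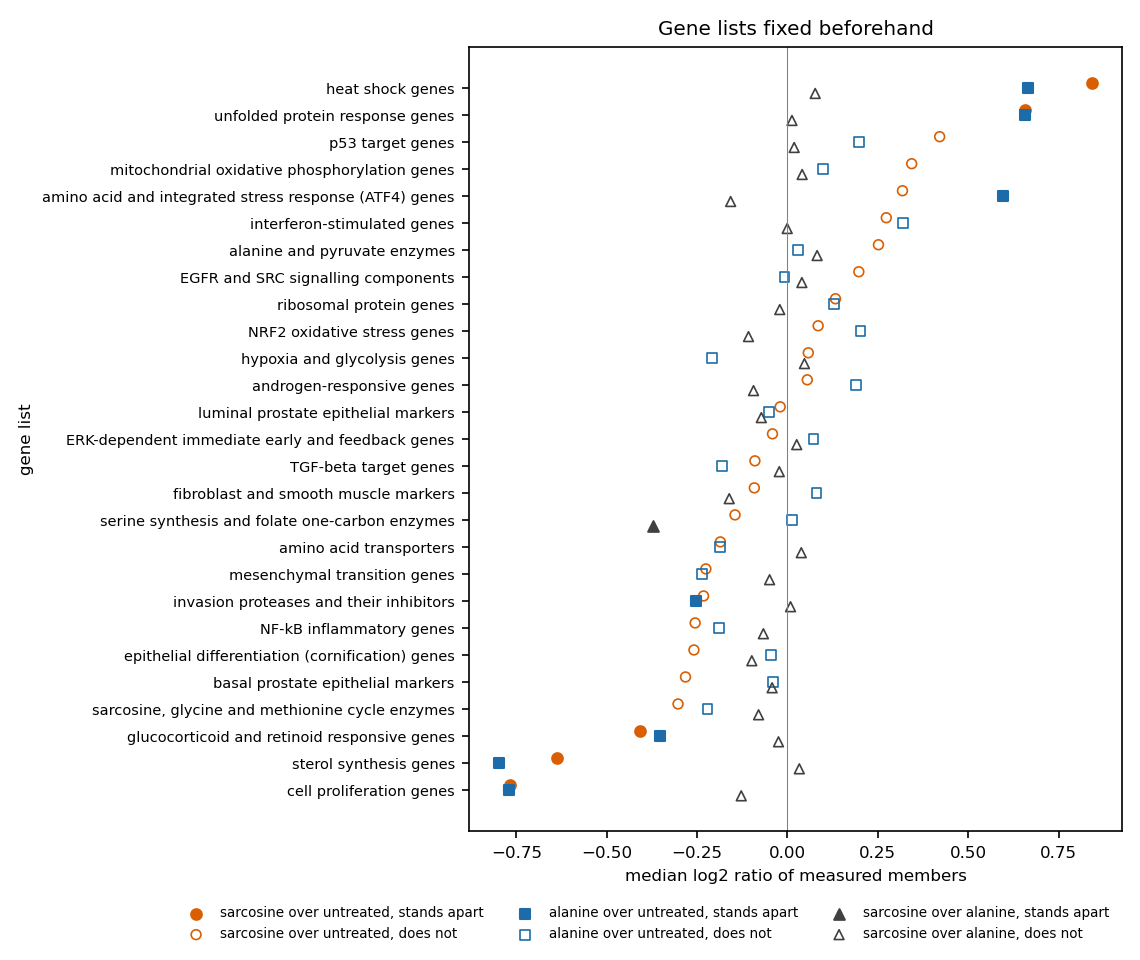
The horizontal axis gives the median log2 ratio of the measured members of each gene list on the vertical axis, for sarcosine over untreated (circles), alanine over untreated (squares) and sarcosine over alanine (triangles), with filled symbols for lists that stood apart. Heat shock genes lie at 0.84 and 0.67 over untreated, and cell proliferation genes at −0.77 and −0.77, but under median centring the latter became 0.32 and 0.13 and every other filled symbol left of 0 moved right of it, as did those of the sterol list with sarcosine, the glucocorticoid list and the invasion list under spike-in scaling.

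Enzymes that make or use sarcosine, glycine and methionine had 2 higher, 3 lower and 8 neither of 13 with sarcosine, at percentile 6.66, and 1 higher, 2 lower and 11 neither of 14 with alanine, at percentile 5.54. MAT2A was higher with both, and ALDH7A1, an aldehyde dehydrogenase, passed with sarcosine at 0.75 ± 0.02. SHMT1, the cytosolic enzyme that moves 1-carbon units from serine, was at −0.82 ± 0.12 with sarcosine, which became 0.10 under median centring, and at −0.74 ± 0.05 with alanine. Their difference was −0.08 ± 0.13, and 0.22 on the other measured probe. The mitochondrial SHMT2 was at −0.15 ± 0.08 and −0.20 ± 0.04, with a difference of 0.04 ± 0.09, and under median centring SHMT2 was at 1.47 and 1.11. The alanine transaminase GPT2 was at −0.14 ± 0.05 and −0.45 ± 0.07, with a difference of 0.31 ± 0.09, but its other probe gave 0.66 and 0.51, and under median centring GPT2 was at 1.17 and 0.37. GCSH, of the glycine cleavage system, was the member that differed between the isomers, at −0.79 ± 0.07. SARDH, DMGDH and GNMT, which break down or make sarcosine, were not well above background on all arrays of any comparison. PIPOX, which oxidises sarcosine, was read on the alanine arrays alone, at −0.25 ± 0.02, or 0.11 under median centring.

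Markers of cell types and of RNA quality were read in the same way. Basal prostate epithelial markers had 4 higher, 5 lower and 8 neither of 17 with sarcosine (percentile 6.54) and 4 higher, 7 lower and 6 neither with alanine (percentile 26.48). Among them TP63 fell with both treatments. Luminal markers had medians of −0.02 and −0.05 over 9 measured genes, and fibroblast and smooth muscle markers −0.09 and 0.08 over 5. Only 1 endothelial, 4 leukocyte and 2 neuroendocrine markers were measured, too few for a percentile. Ribosomal protein genes had medians of 0.13 and 0.13, at percentiles 94.95 and 82.22. Between the isomers these 4 lists with enough members lay at percentiles 73.64, 50.19, 24.38 and 95.17.

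Some genes were read in the treated channel and too dim in the untreated channel. Their fold rests mostly on the dim reading itself, which was not well above background, so it is approximate and no strict lower bound. With sarcosine 126 genes reached 1.5-fold higher on this ground, and with alanine 121. By these readings the RNA helicase gene DDX3X was 4.82-fold higher with sarcosine and 4.80-fold higher with alanine, and the interferon-induced IFIT3 3.57-fold and 2.66-fold. In the other direction 2 genes passed with each treatment. The 2 directions did not have the same number of candidates. With sarcosine 1626 genes were dim in the untreated channel alone and 4 in the treated channel alone, and with alanine 1268 and 16. Treated RNA was always in Cy5, which had more spots well above background on every array. This imbalance of the dyes cannot be told apart from an effect of treatment. MYB, a proliferation-linked transcription factor, came out 1.52-fold lower with sarcosine and 1.60-fold lower with alanine.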

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

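The counts here followed from a rule set beforehand, and none of their tests was chosen after the result was seen. Probes without a gene name lie outside the comparisons of genes, and some of them gave a signal above that of the untreated cells. With sarcosine 357 such probes were higher and 411 lower than untreated, of 2921 measured, by the same size rule as for genes. With alanine 314 were higher and 157 lower, of 3009 measured. Of named genes, each read on its brightest probe, 3169 of 9904 (32.0%) passed with sarcosine and 2854 of 10108 (28.2%) with alanine. These are larger shares than those of the unnamed probes, which thus did not pass unusually often. No biological or technical explanation was tested for them.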

How the results depend on the processing

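Spike-in scaling, values within each slide, centring on measured genes or within intensity bins, the demand on every probe, and the added lists were tests chosen after the results were seen. Against 3169 genes for sarcosine over untreated, 2854 for alanine over untreated and 306 for sarcosine over alanine, median centring gave 7583, 6614 and 1246. Spike-in scaling gave 5758, 3832 and 976. Spike-in scaling adds 1 shift to each array by construction, and median centring put the median of the measured genes at 1.31, 0.94 and 0.31. A 2-fold threshold gave 1281, 1088 and 12, since it asks for more, and array-level limma, which tests array noise alone, gave 8334, 8191 and 4688. Brighter probes alone gave 1898 and 1697 over untreated, since fewer genes were tested, and 255 between the isomers. The demand that every measured probe of a gene passes gave 2643, 2349 and 222. For sarcosine over alanine the scanner's own ratios gave 663, the ratios of the series matrix gave 662, a threshold on the mean of arrays gave 626, slide 1 alone 863 and slide 2 alone 523; fewer conditions had to be met in the last 3, and for the others the cause was not tested. Leaving out 1 array gave 3647 to 3687, 3115 to 3270 and 378 to 596 genes, the last highest without sarcosine replicate 2 (596) and then without alanine replicate 2 (510). The correlation of both ratios was 0.894 to 0.908 with 1 array left out, lowest without sarcosine replicate 2, and 0.901 to 0.91 otherwise.

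The replicate block pairs the arrays that share a replicate number, which per the file headers share a slide. With it, array-level limma gave 5278 genes between the isomers and the size rule on pairs gave 410. The differences of replicate 1 and replicate 2 correlated across genes between the treatments with r = 0.212, and with only 2 pairs this does not settle whether the numbers pair the extracts.

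List medians that changed sign did so mostly under median centring: cell proliferation (0.32 with sarcosine, 0.13 with alanine), sterol synthesis (0.86, 0.50), glucocorticoid and retinoid (1.20, 0.87), invasion proteases (1.01 with alanine), circadian clock (0.43, 0.31) and serine and folate enzymes between the isomers (0.010). Spike-in scaling turned sterol synthesis with sarcosine (0.087), glucocorticoid and retinoid (0.32, 0.018), invasion proteases with alanine (0.12) and circadian clock with sarcosine (0.17). These turns follow from the shift alone and their percentiles stayed the same (0.01, 1.79, 0.97, 2.02 and 0.35). No filter on dim probes turned the last as well (0.020), for which the cause was not tested. Of the genes named and past the size rule, LSS (0.0021), SHMT1 (0.098), PER1 (0.067), DBP (0.17) and BHLHE40 (0.59) with sarcosine turned under median centring. Genes short of the size rule were not counted as turned, and 49 of their values also changed sign, such as SHMT2 (1.47), GPT2 (1.17) and TRIB3 (1.21) with sarcosine under median centring. Heat shock and unfolded protein response lists stood apart under all 14 alternatives run with each treatment, though median centring and spike-in scaling raised their medians, for heat shock genes with sarcosine to 2.42 and 1.57. Among these alternatives, Aquantile and spike-in scaling could not change a percentile. For single genes 1232 values moved by less than 1 SD of the duplicates, 859 by more and 5, all of genes past the size rule, turned. Dim probes set a limit: 1626 genes with sarcosine and 1268 with alanine were too dim in the untreated channel for a ratio.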

Other observations

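The tests of dye bias, of the untreated extract and of short-lived transcripts, and the added lists with all their values, were chosen only after the results were seen, as was the demand that the chaperone list hold within each slide.

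Splicing factors and clock genes were read as 2 added lists, prompted by TRA2B and NR1D1 among the most changed genes. SR splicing factors and CLK kinases had 6 higher and 0 lower of 12 measured with sarcosine, a median of 0.84 and percentile 99.84. Without TRA2B, which prompted the list, the median was 0.51 at percentile 94.22, so the list did not stand apart, nor did it with brighter probes alone (91.94). SRSF1 rose by 1.80 ± 0.06, SRSF5 by 1.62 ± 0.01 and SRSF2 by 1.56 ± 0.05 (SD, n = 2 arrays). With alanine the list had 5 higher and 0 lower of 11, a median of 0.52 and percentile 94.01. Circadian clock genes had 1 higher and 4 lower of 10 with sarcosine, with a median of −0.56 at percentile 0.35 that became 0.43 under median centring, 0.17 under spike-in scaling and 0.02 at percentile 45.62 with no filter on dim probes. Without NR1D1, which prompted this list, the median was −0.49 at percentile 1.2, with 1 higher and 3 lower of 9. DBP was at −1.14 ± 0.10 and BHLHE40 at −0.98 ± 0.10, both above 0 under median centring, while CRY2 rose by 0.79 ± 0.01. PER1, counted as lower, was at −1.48 ± 0.02 on its brightest probe, above 0 under median centring, but at 1.04 on its other probe, and with the mean of a gene's probes the list lay at percentile 8.66. With alanine they had 1 higher and 3 lower of 9, with a median of −0.43 at percentile 1.03 that became 0.31 under median centring and −0.04 at percentile 24.03 with no filter on dim probes, and that without NR1D1 was −0.43 at percentile 1.02. PER2, dim in untreated cells, was 2.53-fold higher with alanine when taken against its dim reading.

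Endoplasmic reticulum chaperones other than HSPA5 and ERP29 had 10 higher and 0 lower of 15 with sarcosine, a median of 0.85 and percentile 100. With alanine they had 8 higher and 0 lower of 16, a median of 0.66 and percentile 99.86. CANX and ERP44 rose with sarcosine, by 1.12 ± 0.11 and 1.18 ± 0.08.

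Against untreated cells, 1390 genes were higher and 754 lower with both sarcosine and alanine. Dye bias of single probes is argued against as the whole cause, since the next probe of the gene had the same sign in 93.2% of 588 genes. Those probes need only not overlap, and dye bias that the probes of a gene share would pass this check. With no dye swapped, such bias stays open. The bend of the loess curve is argued against, since 83.02% of 2144 genes passed under median centring with measured genes put back at 0. That step keeps the level at which loess sets 0, so the share cannot speak to this level. Without the step, median centring left 58 genes lower with sarcosine and 72 with alanine. A difference of the untreated extract in culture or handling cannot be told apart from an effect of both amino acids: the covariance lay 0.395 above that of unchanged extracts, and no other untreated extract was measured. A response to amino acid addition that both isomers share therefore stays open and untested.

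The 306 genes that passed between sarcosine and alanine may hold a part that follows probe intensity, since 70.92% of them passed after centring within intensity bins. This lies between the 50% and 80% set beforehand, so a trend cannot be told apart from a difference of the treatments for the rest. A different strength of the same change is argued against as the whole cause, since 87.58% passed after the slope of 1.08 was removed. Faults of single probes stay open: the next probe had the same sign in 79.35% of 92 genes, just under the 80% set beforehand, with a median size of 0.24 against 0.79. A difference between the treatments stays open as well.

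HERPUD1, ERN1, ATF3 and TRIB3 were lower with sarcosine and ERP29 and PDIA3 higher, though the unfolded protein response list did not stand apart (percentile 82.36), and as a hypothesis chaperone genes may be higher as a class. HERPUD1, ERN1, ATF3 and ERP29 were each read on 1 probe. The chaperone list had a median of 0.17 at percentile 98.89 between the isomers, but 0.09 and 0.08 at 93.52 and 93.77 within the slides, 0.09 to 0.12 at 94.37 to 96.28 with 1 array left out and 0.12 at 95.9 with brighter probes alone. After a scale step it was 0.03 at 87.96. Of the alternatives run, 10 kept the chaperone list apart and 8 did not. Aquantile and spike-in scaling, among the 10, could not change the percentile, and the series matrix ratios repeat the scanner's own. The tally is thus no measure of support, and the hypothesis stays open. HSPA5, which drew attention to the pattern, is higher on 1 of its 2 probes. Whether short-lived transcripts were lower with sarcosine stays open. The immediate early list lay at percentile 86.15, but its genes were picked for control by ERK and not for how long their transcripts last.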
